A study of Homo sapiens with 4 samples.

How the data were processed

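RNA of 4 human mammary epithelial cell lines was sequenced by the authors, with 1 library per line and therefore no replicates. Per the labels' protocols, total RNA was treated with DNase, libraries were made with a stranded total RNA kit that removes ribosomal RNA, and sequencing was done on a MiSeq. Also per the labels, HCC1954 was grown in RPMI medium with serum, and the other 3 lines in a mammary epithelial growth medium. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0 and Cuffdiff were used with the hg19 and GRCh37 builds. Their settings and order are not given in the sources used here.

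The unit of every value is FPKM, per the file headers, and 1 unstranded and 1 stranded FPKM per locus was deposited for each of 90 HML-2 loci in each line. The deposited series tables, which are labelled as unique reads, held the same numbers, with 0 of 720 values different. They list FPKM only, so no fold change or p-value of the authors was used. Unstranded FPKM was the main measure. Uniquely placed reads undercount proviruses that share long identical stretches with other copies, and an unstranded value adds reads of a host gene to those of the provirus.

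FPKM values came in whole multiples of the step of 1 fragment once a fixed length was taken off each locus. This length and the step were fitted per line on loci listed in intervals of up to 11000 bp. The fitted length was 201 bp in HCC1954, HMLE-Ras and HME and 654 bp in HMLE-Her2. Of 62 values above 0 at such loci, 61 (98.4%) lay within 0.1 fragment or 1% of a whole number. The 0.1 rule alone would pass 20% of values of random fraction. That is no fair benchmark, since the 1% rule passes more at large numbers and the length and step were fitted on these same values. At 21 loci listed inside longer intervals the counted length is not known from the interval, so it was solved as a length that makes all values whole, and all 36 values above 0 there then lay within that tolerance by this construction. At 10p14 the lengths that fit, 7519 to 7535 bp against a matched span of 9465 bp, give 1 set of fragment numbers. Among the named loci only 19q13.12b had another, at about double the length and the fragments (18820 to 18825 bp), and the shortest length was used. At 11q12.3 HCC1954 has 16 or 17 fragments. Only 3q21.2, of the 42 loci with a value, was not whole in every line. Its nearest whole numbers enter the totals, and it has no interval of its own. Fragment numbers are therefore inferred rather than read from a table of counts.

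The stranded values of each line lie on a scale that differs from the unstranded one by a constant, 1.28 in HCC1954, 1.18 in HMLE-Ras, 1.09 in HMLE-Her2 and 1.25 in HME. The sense share of a locus is its stranded value divided by this constant and by its unstranded value. The files do not say which strand the stranded values count. They were taken as sense to the provirus. Read this way, at 8 proviruses opposite to a protein-coding gene and under no gene of their own strand, 8 of 229 fragments lie on the strand of the provirus and the rest on the strand of the gene. This sets the orientation and is no separate test of it.

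Locus positions were read as starting at base 0 in the files and are given from base 1. Where an interval was longer than 11000 bp, the provirus inside it was placed with blastn 2.17.0, with 1q22 as the query. Strand came from the same match. Genes were taken from GENCODE 44 lifted to GRCh37. The share of windows of 75 and 150 bases that occur once in the genome was counted for each locus. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9.

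Before the data were examined, the comparisons, the 2-fold rule, the lists and the alternatives were fixed, while the fragment recovery, its intervals and the added alternatives named in the closing section came afterwards. A locus counted as detected at an FPKM of 1 or more. For each pair of lines, loci at an FPKM of 1 or more in either line were called higher or lower at a log2 fold of at least 1 on log2(FPKM + 0.1), which understates the difference of low loci. No test was run between lines. Intervals are exact 95% Poisson intervals for fragment numbers, Clopper-Pearson intervals for shares, and the exact binomial interval for the ratio of fragment rates. At single loci the ratio printed before such an interval is of FPKM. In comparisons with HMLE-Her2, whose fitted length differs, the FPKM ratio is not the fragment rate ratio that the interval covers. A locus at 0 was compared at a floor of 3 fragments per library, which leaves out counting error in the other line, so the exact bound is given beside it.

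Loci were named if they were among the 5 highest in any line, or among the 5 largest increases or decreases against HME with an FPKM of at least 1 in either line, or at 1 or more in exactly 1 line (the 3 highest per line) or in all lines (the 5 highest), or members of a fixed list at 1 or more in any line. This gave 12 loci. The lists hold 16 human-specific proviruses, 6 with a long env reading frame and 9 reported in tumour cells. The provirus 19p12b, a member of the first 2 of them, was not analysed here, and 1p31.1 was taken as the longer of the copies listed at that band. Percentiles of the list medians among 10000 random lists were computed and are not given, since the members at the median hold at most 1 fragment in the lines compared. Planned marker genes were not analysed here, since the values cover HML-2 loci only.

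The recovery and the 2-fold rule were tested on simulated data, with 20 runs of 90 loci drawn at the depths of HCC1954 and HME. Of 801 simulated values, 98.5% gave the right fragment number, and the fitted length was off by at most 72 bp. The simulated values followed the same model of step and length, so this tests the fit and not the model. Recovery was scored only at loci in intervals of up to 11000 bp, and HMLE-Her2 was not simulated. In that comparison the rule called 48.1% of loci changed 2-fold, 96.2% of those changed 4-fold and 100% of those changed 8-fold, and 5.88% of unchanged loci, among loci at an FPKM of 1 or more.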

Results

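Transcription of the HML-2 group of human endogenous retrovirus K, the youngest group of endogenous retroviruses in the human genome, was measured in 4 human mammary epithelial cell lines. HME is labelled immortalized and non-transformed. HMLE-Ras, HMLE-Her2 and HCC1954 are labelled tumorigenic, and HCC1954 is an established breast carcinoma line. Total RNA depleted of ribosomal RNA was sequenced from 1 library per line, and an FPKM value was listed for each of 90 HML-2 loci. The values could be traced back to 338 fragments at HML-2 loci in HCC1954 (exact Poisson 95% interval 303 to 376), 271 in HMLE-Ras (240 to 305), 78 in HMLE-Her2 (61.7 to 97.3) and 178 in HME (153 to 206). The step of 1 fragment puts the total behind the per-million scale at 2361000 fragments in HCC1954, 1700000 in HMLE-Ras, 1772000 in HMLE-Her2 and 1769000 in HME, to the nearest 1000. This implied total is called depth here and need not equal the number of fragments sequenced. At this depth an FPKM of 1 over 9 kb corresponds to between 14.8 and 20.8 fragments. No line was sequenced in replicate, so differences between lines have no replicate check, and all intervals cover counting error only.

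The first question was how many proviruses were transcribed in each line and how strongly. HMLE-Ras had 10 loci at an FPKM of 1 or more, HCC1954 had 7, HME had 4 and HMLE-Her2 had 1. Summed over loci, HML-2 reached an FPKM of 24.7 in HMLE-Ras and 22.7 in HCC1954, against 14.7 in HME and 6.44 in HMLE-Her2. Relative to HME, the rate of HML-2 fragments was 1.58 in HMLE-Ras (exact 95% interval 1.31 to 1.93), 1.42 in HCC1954 (1.18 to 1.72) and 0.437 in HMLE-Her2 (0.331 to 0.574). On the strand of the provirus alone and on the same scale, the sum was 7.59 in HCC1954, 7.50 in HMLE-Ras, 3.21 in HMLE-Her2 and 3.01 in HME. This takes the stranded values as sense, which the files do not state, and with the orientation turned the sums were 15.1, 17.2, 3.23 and 11.7. The rate of sense fragments relative to HME was 2.31 in HCC1954 (1.57 to 3.46), 2.51 in HMLE-Ras (1.69 to 3.82) and 1.28 in HMLE-Her2 (0.807 to 2.03). Without 1q22 the sense sum was 0.759 in HMLE-Her2 and 1.56 in HME, so the order of these lines turned, and it was 4.82 in HMLE-Ras and 7.59 in HCC1954, where 1q22 was listed at 0. Then the ratios of sense fragments were 6.40 in HCC1954 (3.59 to 12.4), 3.68 in HMLE-Ras (1.956 to 7.43) and 0.691 in HMLE-Her2 (9 fragments against 13, 0.261 to 1.75).

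The highest loci differed between lines, and the 3 highest together held 46.1% of the summed FPKM in HCC1954, 32.9% in HMLE-Ras, 56.8% in HMLE-Her2 and 52.9% in HME. In HCC1954 the highest locus was 7q34, at an FPKM of 5.21 and 23.0% of the sum. In HMLE-Her2 it was 1q22, at 2.45 and 38.0%, and in HME it was 10p14, at 3.32 and 22.5%. In HMLE-Ras the highest value was 2.75 at 12q24.11, 11.1% of the sum, but this locus is only 1483 bp long and the value rested on 6 fragments (1.01 to 5.99). Next in HMLE-Ras came 1q22 at 2.69 with 41 fragments and 9q34.11 at 2.68 with 32. The ranking depends on how unique each locus is in the genome. With FPKM divided by the share of unique 75-base windows, 12q24.33 was highest in HCC1954 (48.1% of the sum), HMLE-Ras (28.1%) and HME (38.1%), and 1q22 in HMLE-Her2 (51.5%). Only 4.38% of these windows are unique at 12q24.33, so its value in HCC1954 rose from 1.38 to 31.6. It rests on 19 fragments in HCC1954, 12 in HMLE-Ras and 9 in HME. Exons of ZNF140 overlap this locus on the opposite strand. With 150-base windows 12q24.33 was highest in HCC1954 (29.3%) and HME (25.5%), and 1q22 in HMLE-Ras (20.4%, against 19.2% at 12q24.33) and HMLE-Her2 (50.2%). Of the 90 loci, 48 were listed at 0 in all 4 lines, 12 reached an FPKM of 1 in any line, and 0 reached it in all lines. Loci listed above 0 in a single line numbered 10 in HCC1954, 4 in HMLE-Ras, 1 in HME and 0 in HMLE-Her2. Of these, 6 in HCC1954, the library with the largest implied total, 3 in HMLE-Ras and 1 in HME rested on 1 fragment.

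The library kit keeps strand, so it could be asked which proviruses were read in their own orientation, with the stranded values taken as sense to the provirus. This orientation is an assumption, since the files do not state it. Only 3 of the 12 loci at an FPKM of 1 or more were read mainly in the sense of the provirus, namely 1q22, 3q12.3 and 1q21.3. At 1q22 all 41 fragments in HMLE-Ras, all 37 in HMLE-Her2 and all 23 in HME were sense. At 3q12.3 all 58 fragments in HCC1954 and all 23 in HMLE-Ras were sense, and at 1q21.3 16 of 17 fragments in HCC1954 and 8 of 10 in HMLE-Ras were. Together these loci held 66.7% of the sense fragments in HCC1954, 82.8% in HMLE-Ras, 95.7% in HMLE-Her2 and 80.6% in HME.

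The other 9 loci were read mainly antisense to the provirus. At 7q34, 0 of 47 fragments in HCC1954 were sense (Clopper-Pearson upper bound 7.55%). At 9q34.11 the count was 0 of 37 in HME (up to 9.49%) and at 10p14 it was 0 of 43 in HME (up to 8.22%). Over all loci, the sense share of fragments was 32.8% in HCC1954 (Clopper-Pearson interval 27.9 to 38.1%), 32.1% in HMLE-Ras (26.6 to 38.0%), 59.0% in HMLE-Her2 (47.3 to 70.0%) and 20.2% in HME (14.6 to 26.9%). The locus 1q22 set much of this order, since without it the share was 20% in HMLE-Ras, 21.95% in HMLE-Her2 and 8.39% in HME. It was unaltered in HCC1954, where 1q22 was listed at 0. With the orientation turned, the shares were 67.2%, 67.9%, 41.0% and 79.8% in HCC1954, HMLE-Ras, HMLE-Her2 and HME. The rate relative to HME was then 1.20 in HCC1954 (0.967 to 1.49, which includes 1), 1.35 in HMLE-Ras (1.08 to 1.69) and 0.225 in HMLE-Her2 (32 fragments against 142, 0.148 to 0.332). Counted on the sense strand alone in the assumed orientation, the number of loci at an FPKM of 1 or more was 3 in HMLE-Ras, 2 in HCC1954, 1 in HMLE-Her2 and 1 in HME. This count was not made with the orientation turned, so the order of lines by it depends on the assumption.

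**Figure D1:**
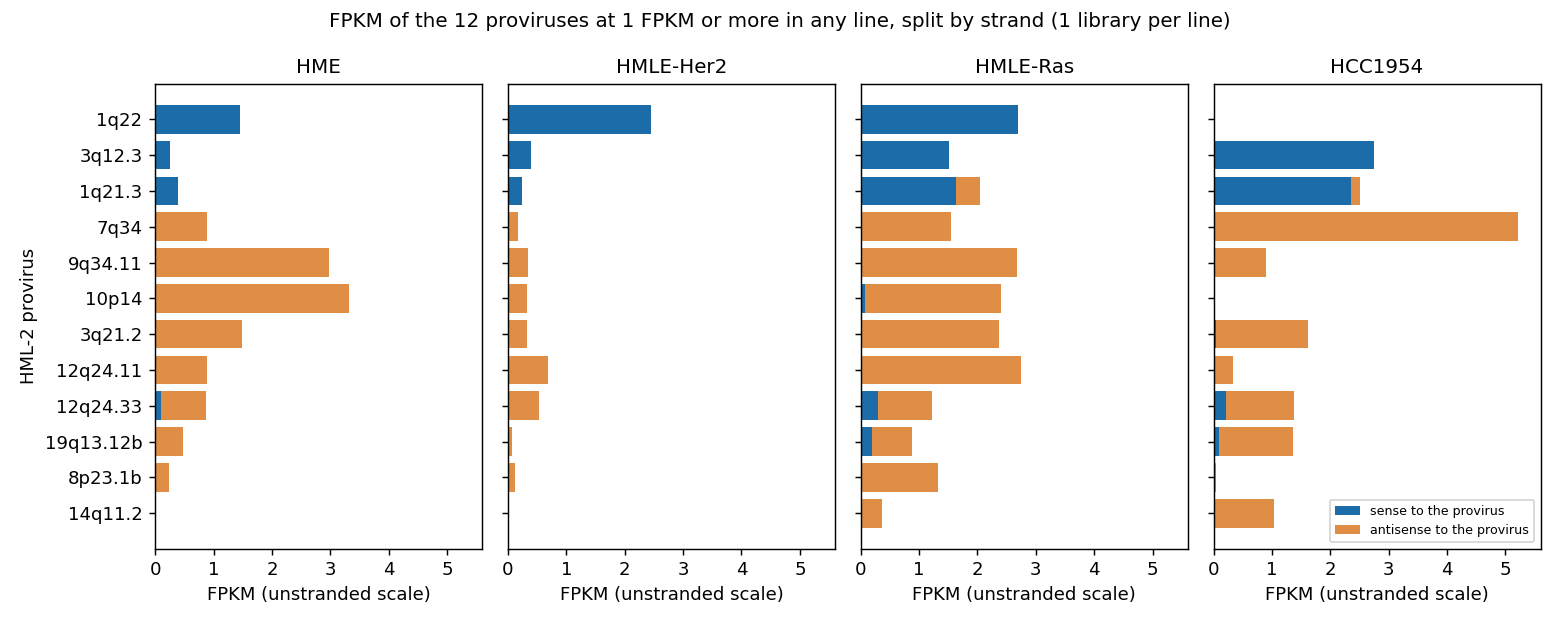
FPKM (horizontal axis, on the unstranded scale) of the 12 proviruses at an FPKM of 1 or more in any line, 1 panel per cell line and 1 library each, with the bar divided into signal sense and antisense to the provirus. Most of the sense signal lies at 1q22, 3q12.3 and 1q21.3, with smaller sense parts at 12q24.33, 19q13.12b, 10p14 and 3q21.2. In HCC1954 1q22 has no bar, while the bar of 7q34 (5.21) is all antisense.

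The position of these loci differed. On GRCh37, 1q22 lies on chromosome 1 at 155596457 to 155605636, on the minus strand, under exons of an unnamed long non-coding RNA gene of the same strand. The provirus 3q12.3 lies on chromosome 3 at 101410737 to 101419859, on the plus strand, and overlaps exons of the transcribed pseudogene PDCL3P4 on that strand. The locus 1q21.3 lies on chromosome 1 at 150605284 to 150608361, on the minus strand, with only an unnamed long non-coding RNA gene annotated over it, on the opposite strand. By contrast, 7q34 (chromosome 7, 141451918 to 141455938, minus strand) lies in an intron of SSBP1, which encodes a mitochondrial single-stranded DNA-binding protein and is transcribed from the other strand. In the same way 9q34.11 (chromosome 9, 131612515 to 131619736, plus strand) lies in an intron of KYAT1, a kynurenine aminotransferase gene, and 12q24.11 (chromosome 12, 111007843 to 111009325, plus strand) in an intron of PPTC7, a protein phosphatase gene, both on the opposite strand. An intron of the long non-coding RNA gene LINC00707 covers 10p14 (chromosome 10, 6866139 to 6875603, minus strand) on the opposite strand, and an intron of LINC02614 covers 3q21.2 (chromosome 3, 125609301 to 125618416, plus strand). Both also have a gene on their own strand, exons of an unnamed long non-coding RNA gene at 10p14 and the pseudogene ENPP7P4 at 3q21.2. The remaining antisense loci also had genes on the opposite strand, namely ZNF140 at 12q24.33 (chromosome 12, 133667122 to 133673059, minus strand), DHRS4L1 at 14q11.2 (chromosome 14, 24480625 to 24484121, minus strand), FAM85B at 8p23.1b (chromosome 8, 8054700 to 8064221, plus strand) and ZNF420 at 19q13.12b (chromosome 19, 37597549 to 37607066, minus strand). Genes of the same strand as the provirus were annotated at 14q11.2 (DHRS4-AS1), at 8p23.1b (ENPP7P1 and exons of an unnamed long non-coding RNA gene) and at 19q13.12b (ZNF585A).

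Against HME, HCC1954 differed at 8 of the 10 loci that reached an FPKM of 1 in either line. By the rule of a 2-fold difference on log2(FPKM + 0.1), 5 loci were higher (3q12.3, 1q21.3, 7q34, 19q13.12b and 14q11.2), 3 were lower (1q22, 10p14 and 9q34.11), and 2 were neither (12q24.33 and 3q21.2). The ratio was 10.9 at 3q12.3 (58 fragments against 4, exact interval 4.02 to 41.2), 6.37 at 1q21.3 (1.51 to 56.8) and 5.87 at 7q34 (2.503 to 16.8). At 19q13.12b, which overlaps exons of the zinc finger genes ZNF420 and ZNF585A on opposite strands, the ratio was 2.81 (1.26 to 7.09). The locus 14q11.2 was listed at 1.03 in HCC1954 and at 0 in HME, 1.997-fold higher when HME is set to a floor of 3 fragments, with an exact lower bound of 1.28. In the other direction, 1q22 was listed at 0 in HCC1954 and 1.45 in HME, 10.2-fold lower at the same floor with an exact lower bound of 7.67, and 10p14 at 0 against 3.32, 19.1-fold lower at the floor with a bound of 14.9. At 9q34.11 HCC1954 had 0.905 against 2.98, 3.29-fold lower (1.76 to 6.46). HCC1954 was grown in another medium than the other lines, so medium and line cannot be told apart. After scaling both lines to the same summed FPKM, 3 loci instead of 5 were higher.

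HMLE-Ras was higher than HME at 4 of 10 loci and lower at 0. The loci were 3q12.3 with a ratio of 5.98 (2.04 to 23.8), 8p23.1b with 5.46 (1.84 to 21.9), 1q21.3 with 5.20 (1.11 to 48.8) and 12q24.11 with 3.12 (0.558 to 31.6). The last interval includes 1. At 1q22 the FPKM was 2.69 against 1.45, a ratio of 1.86 (1.09 to 3.24) that stayed under the 2-fold rule. The antisense loci with high values in HME were close to it, with ratios of 0.726 at 10p14 (0.440 to 1.18) and 0.900 at 9q34.11 (0.543 to 1.48). With a pseudocount of 1, and also after scaling to the same summed FPKM, 2 loci were higher instead of 4.

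HMLE-Her2 was higher than HME at 0 of 4 loci and lower at 3, all of them antisense loci. At 10p14 it had 0.328 against 3.32, 10.1-fold lower (3.91 to 41.3). At 9q34.11 it had 0.344 against 2.98, 8.67-fold lower (3.33 to 35.8), and at 3q21.2 it had 0.333 against 1.49, 4.48-fold lower. No interval is given for 3q21.2 because its values were not whole fragment numbers. The sense locus 1q22 was listed at 2.45 in HMLE-Her2, an FPKM ratio of 1.69, and the interval of its fragment rate ratio (0.929 to 2.83) includes 1. The FPKM ratios to HME also carry the longer fitted length of HMLE-Her2, which the intervals leave out. At 1q22 that length raises the FPKM 1.05-fold. Scaled to the same summed FPKM, 2 loci were higher than in HME instead of 0, and counted on the sense strand alone 0 were lower instead of 3. The 3 loci had a stranded value of 0 in both lines, so they could not be lower by it. With the orientation turned they keep their full values in both lines.

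**Figure D2:**
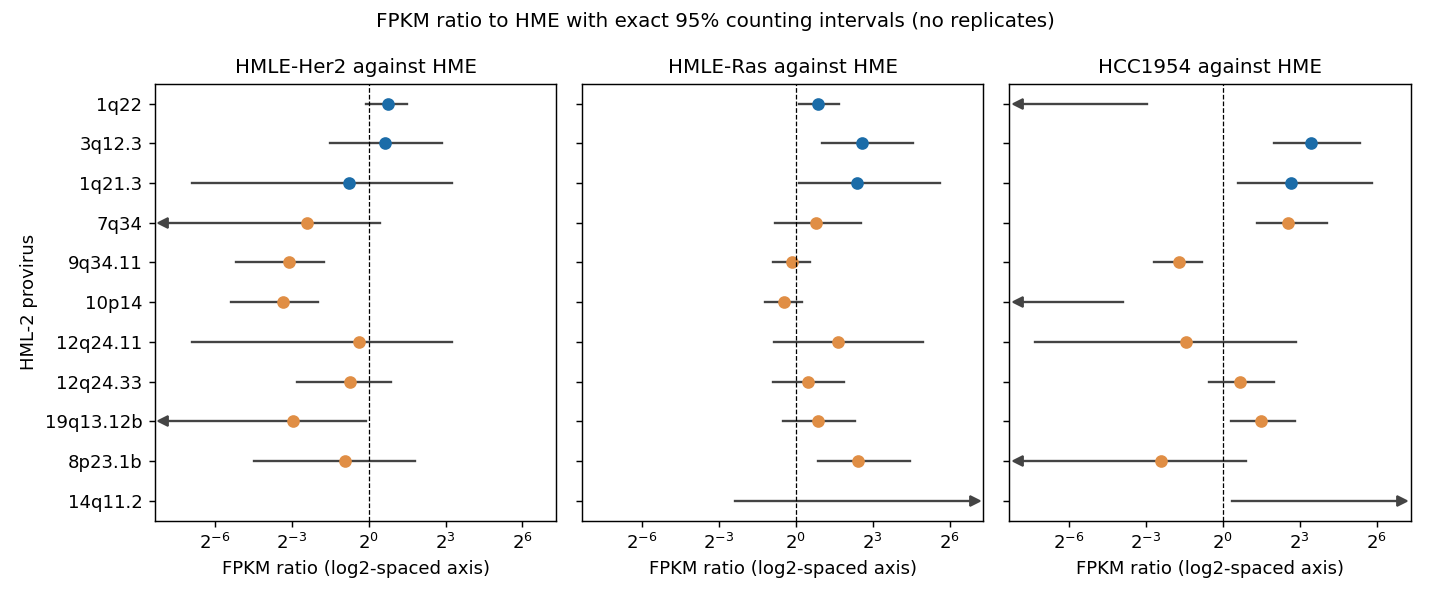
Ratio of FPKM to that in HME (horizontal axis, log2-spaced, dashed line at 1) for the named proviruses with whole fragment numbers, 1 panel per tumorigenic line. Points are FPKM ratios where both lines were above 0, coloured blue for 1q22, 3q12.3 and 1q21.3 and orange for the others, lines are exact 95% intervals of the fragment rate ratio, and arrowheads are bounds beyond the axis. In HCC1954 1q22 and 10p14 have only an upper bound, far below 1, while 3q12.3 lies at 10.9.

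The tumorigenic lines also differed from each other. Between HCC1954 and HMLE-Ras, 2 loci were higher in HCC1954 (7q34 and 14q11.2), 5 were lower (1q22, 10p14, 8p23.1b, 9q34.11 and 12q24.11) and 5 were neither. The FPKM at 7q34 was 3.38-fold higher in HCC1954 (1.69 to 7.51), and 8p23.1b was 29.2-fold lower, with 1 fragment against 21 (4.69 to 1207). At 3q12.3 both lines were high, at 2.75 and 1.52, a ratio of 1.82 (1.10 to 3.08). Against HMLE-Her2, HCC1954 was higher at 7 of 8 loci and lower only at 1q22, and HMLE-Ras was higher at 9 of 10 loci, with 1q22 at a ratio of 1.10 (0.723 to 1.85). In both comparisons 3q21.2 is among the higher loci and has no interval. The exact interval excluded 1 at all 6 higher loci with an interval in HCC1954 and at 6 of 8 in HMLE-Ras. After scaling to the same summed FPKM, the loci higher than in HMLE-Her2 were 3 in HCC1954 and 2 in HMLE-Ras.

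Across the 42 loci with a value in any line, the 3 lines of the shared medium were closest to each other. Spearman's rho of FPKM was 0.755 between HMLE-Her2 and HME (Pearson's r of log2(FPKM + 0.1) 0.814), 0.709 between HMLE-Ras and HMLE-Her2 (0.796) and 0.703 between HMLE-Ras and HME (0.827). HCC1954 had a rho of 0.422 with HMLE-Her2 (r 0.343), 0.335 with HME (0.377) and 0.275 with HMLE-Ras (0.462). These correlations run across loci, which are not independent replicates. Over the 12 loci at an FPKM of 1 or more in any line, rho with HCC1954 was negative for all 3 lines. Keeping only loci high in some line drops those low in both, which can lower rho, and 12 loci are few.

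Proviruses of 3 lists fixed in advance were looked at as groups. Of 15 human-specific proviruses, the insertions found only in humans, 10 were listed at 0 in all lines and 1 reached an FPKM of 1, which was 1q22. Of 5 proviruses known for a long env reading frame, 2 were above 0 in any line and 0 reached an FPKM of 1. Of 9 proviruses reported as transcribed in tumour cells, 5 were above 0 and 3 reached an FPKM of 1, namely 1q22, 3q12.3 and 3q21.2. These loci are hard to read uniquely, with a median of 17.3% unique 75-base windows in the human-specific list, 10.2% in the long env list and 19.2% in the tumour cell list, against 67.7% at all loci listed at 0 and 82.6% at all loci with a value. Against HME, the median log2 fold of members above 0 in any line was 0.71 in HMLE-Ras for each list and 0 in HCC1954 and HMLE-Her2. The value of 0.71 comes from 8p23.1a and 7p22.1b, each with 1 fragment in HMLE-Ras and 0 in HME. In the human-specific and long env lists it is therefore set by the pseudocount and carries no information on them. In the tumour cell list it lies between 0.848 at 1q22 (41 fragments against 23) and 0.637 at 3q21.2 (36 against 24). The other members were at 2.19 (3q12.3) and -0.887 (17p13.1).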

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

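The tests of the 1q22 result and of the antisense signal were chosen after the results were seen. The provirus 1q22 stood out because lines differed from HME in opposite directions, each with a counting interval that excludes 1. In HMLE-Ras its ratio of 1.86 (1.09 to 3.24) is near that of the summed FPKM, 1.68. Only 11.3% of 75-base and 27.4% of 150-base windows at 1q22 are unique, so placement of its fragments is less sure. The log2 fold against HME was 0.85 in HMLE-Ras and -3.95 in HCC1954, where the second value depends on the pseudocount because the locus was listed at 0. The difference between the lines was not tested.

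A shortage of sampled fragments in HCC1954 is argued against, since the rate in HME would give 30.7 fragments at the depth of HCC1954, and the Poisson probability of 0 is then 4.61e-14. Growth medium stays open, because 0 lines were grown in both media and HCC1954 is the only line in its medium. A rearranged or variant copy of the locus in HCC1954, and a difference in regulation between the lines, were not tested and remain possible too.

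The other pattern to follow up is that 585 of 865 fragments over all lines were antisense to the provirus. An inverted strand setting stays open. The orientation was itself set by reads at proviruses opposite to protein-coding genes. Of the proviruses under a gene of their own strand only, 6 of 10, or 60% (26.2 to 87.8%), were mostly sense. This count weighs 15q25.2, with 1 fragment, like 1q22, so it could not decide it. There, 210 of 234 fragments were sense (85.1 to 93.3%), most of them at 1q22 and 3q12.3. In the orientation used here, transcripts of genes on the opposite strand may account for part of the pattern. By fragments, the sense share was 17.1% under opposite-strand genes only, 89.7% under same-strand genes only, 3.48% under genes on both strands and 19.3% under no gene. Without the loci that set the orientation, the share by fragments under opposite-strand genes only was 70.7% (41 of 58, 57.3 to 81.9%), 27 of the 41 from 1q21.3. The mean share per locus was then 50.2% over 5 loci under opposite-strand genes only and 57.3% over 10 under same-strand genes only, a difference of -7.05 percentage points with p = 0.840 (two-sided exact permutation test), which leaves this open. Annotated opposite-strand genes do not cover all antisense fragments as placed, since 70, or 11.97% (9.45 to 14.9%), lay at proviruses with no such gene. Of these, 27 lay at 8p23.1c, 11 at 6p22.1, 10 at 8p23.1d and 8 at 11p15.4. The interval treats fragments as independent, which fragments of 1 locus are not. Only 12.7% of 75-base windows at 8p23.1c and 9.94% at 8p23.1d are unique, so placement there is less sure than at 6p22.1 (96.9%).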

How the results depend on the processing

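The length offset, unique-window, fragment-minimum, exact-interval, common sense scale, turned orientation and 1q22 alternatives were chosen after seeing the data. No paired analysis was possible because each line has 1 library. Of the values that answer a comparison, 134 recomputed values stayed and 107 did not. For sums and shares, staying meant within counting error, and for counts within 1.5 times. For list medians it meant within a bootstrap interval over members, and for rho within an approximate interval across loci. Some of the 134 could not move, since the unstranded series table holds the main values and a common length offset of 201 bp alters only HMLE-Her2. Changes of direction were not scored for these values. The cause of a move was not tested unless the alternative's construction gives it. Detected loci in HCC1954, HMLE-Ras, HMLE-Her2 and HME were 24, 21, 13 and 14 at a threshold of 0.1, 3 and 8 in HMLE-Her2 and HME at 0.5, 1, 0, 0 and 0 at 5, and 2, 3, 1 and 1 by stranded values. In the same order the summed FPKM was 9.71, 8.86, 3.51 and 3.75 by stranded values as deposited, whose scale differs between lines, 7.59, 7.50, 3.21 and 3.01 by sense values on the unstranded scale, which turns the order of HMLE-Her2 and HME through 1q22 (0.759 and 1.56 without it) if the assumed orientation holds, 15.1, 17.2, 3.23 and 11.7 with the orientation turned, 15.9, 20.5, 2.45 and 9.24 over loci at 1 or more, and 65.7, 98.8, 41.9 and 52.4 per unique 75-base window, or 35.8, 47.9, 17.8 and 26.0 with 150 bases. Without the highest locus it was 17.5 in HCC1954, 3.99 in HMLE-Her2 and 11.4 in HME. The share of the highest locus was 36.3, 35.8, 76.3 and 48.1% by stranded values, where it was 3q12.3 in HCC1954 and 1q22 in the other lines. It was 48.1, 28.1, 51.5 and 38.1% per unique 75-base window, where it was 12q24.33 in all lines but HMLE-Her2, and it was 50.2% at 1q22 in HMLE-Her2 with 150 bases. Without a filter on low values, the loci higher and lower were 17 and 6 for HCC1954 against HME, 11 and 2 for HMLE-Ras against HME, 7 lower for HMLE-Her2 against HME, 12 and 8 for HCC1954 against HMLE-Ras, 21 and 2 for HCC1954 against HMLE-Her2, and 20 and 1 for HMLE-Ras against HMLE-Her2. Scaled to the same sum, 3 were higher for HCC1954 against HME, 2 higher and 1 lower for HMLE-Ras against HME, 2 higher for HMLE-Her2 against HME, 1 higher for HCC1954 against HMLE-Ras, 3 higher and 2 lower for HCC1954 against HMLE-Her2, and 2 higher and 1 lower for HMLE-Ras against HMLE-Her2. By stranded values they were 2 and 1 for HCC1954 against HME, 2 higher for HMLE-Ras against HME, 0 lower for HMLE-Her2 against HME, 0 and 1 for HCC1954 against HMLE-Ras, and 2 higher for each of HCC1954 and HMLE-Ras against HMLE-Her2. Sense values on the unstranded scale gave the same counts of detected loci, 2, 3, 1 and 1, and of higher and lower loci in each of these pairs. A pseudocount of 1 gave 2 higher for HMLE-Ras against HME and 1 for HCC1954 against HMLE-Ras, where at least 10 fragments in either line, or an exact interval that excludes 1, also gave 1. The same interval rule left 5 higher and 3 lower for HCC1954 against HME, 3 higher for HMLE-Ras and 2 lower for HMLE-Her2. The median log2 fold in HMLE-Ras against HME was 2.88 with a pseudocount of 0.01 for the human-specific and the long env lists, and for the latter 0.089 with a pseudocount of 1 and 0 without a filter. Spearman's rho over the 12 loci at 1 or more was -0.270 for HCC1954 and HME, -0.378 for HCC1954 and HMLE-Ras, -0.189 for HCC1954 and HMLE-Her2, and 0.448 for HMLE-Her2 and HME. The sign with HCC1954 thus turned, but over 12 loci kept for their high values, which can lower rho. Of the folds of single loci, 147 recomputed values stayed and 9 did not, while 0 folds that met the 2-fold size changed direction. Staying meant within counting error, except at 3q21.2, which has no interval and was held to a log2 difference under 0.5. Here too the 147 include values that could not move. Among the 9 was 10p14 in HMLE-Ras against HME, which was 0.96 instead of -0.45 by stranded values that rest on 1 sense fragment. Without 1q22 the sense share was 20% in HMLE-Ras, 21.95% in HMLE-Her2 and 8.39% in HME, and with the orientation turned it was 67.2% in HCC1954, 67.9% in HMLE-Ras, 41.0% in HMLE-Her2 and 79.8% in HME. At this depth the floor of 3 fragments over 9 kb is an FPKM of 0.144 in HCC1954, 0.201 in HMLE-Ras, 0.203 in HMLE-Her2 and 0.193 in HME, up to which a locus listed at 0 cannot be told from one that is transcribed.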

Other observations

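The test of locus length and the count of loci with mostly unique windows were chosen after the result was seen, while the comparison of unique windows was set before the windows were counted, though the set of loci it is applied to was reworded afterwards. Outside the named loci, chosen after their values were seen, 8p23.1c (chromosome 8, 12073970 to 12083497, minus strand) and 6p22.1 (chromosome 6, 28650367 to 28660735, plus strand) have no annotated gene over them and were read antisense. The FPKM at 8p23.1c was 0.636 in HCC1954, 0.568 in HMLE-Ras, 0.191 in HMLE-Her2 and 0.0606 in HME, on 14, 9, 3 and 1 fragments. At 6p22.1 it was 0.458 in HCC1954, on 11 fragments, and 0 in the other lines. Of the 75-base windows, 12.7% at 8p23.1c and 96.9% at 6p22.1 are unique.

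The 48 loci listed at 0 in all lines may in part reflect reads that match several places in the genome. The median share of unique 75-base windows was 67.7% at these loci and 82.6% at loci with a value, a difference of -15.0 percentage points with p = 0.187 (two-sided permutation test), which does not settle it. Loss of such reads is argued against for 22 of the 48, where at least 80% of windows were unique. The 22 include Yp11.2 (90.95% unique) on chromosome Y, and whether these lines carry that chromosome was not tested. Shorter loci could also catch fewer fragments, and the median length was 6127 bp against 8064 bp, a difference of -1937 bp with p = 0.0730 (two-sided permutation test), so this stays open as well. Yq11.23a and Yq11.23b, also on chromosome Y, are among the 48 too. Neither comparison of medians was repeated without the loci of that chromosome. No biological explanation was tested.

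The length taken off each locus before FPKM was computed was 654 bp in HMLE-Her2 and 201 bp in the other lines. With 201 bp in all lines, an alternative chosen after seeing the data, the summed FPKM of HMLE-Her2 was 5.84 instead of 6.44, and 12q24.11 was 0.440 instead of 0.681 there.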
